A study of Homo sapiens with 28 samples.

How the data were processed

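RNA was measured in cultured human fibroblasts by strand-marking RNA sequencing of polyadenylated RNA, per the labels' protocols. The series holds 28 libraries of 7 fibroblast lines. The keloid lines were CRL-1762, PK1, PK2, PK3 and PK4, and the normal lines were PCS-201-021 and PNF4. An alternative with patient-derived lines left out CRL-1762 and PCS-201-021, and so kept PNF4 as the only normal line. Each line was treated with DMSO, the solvent control, or with 1 µM corin for 24 h, with 2 libraries per line and treatment. Every sample was grouped by its label, and 0 sample columns of the tables were left unused.

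The deposited count table holds whole-number read counts per gene, not normalized, for 60646 Ensembl genes. Per the submitters' processing notes, the tools included FastQC 0.11.7, STAR 2.7.9a, featureCounts, Subread 2.0.3 and DESeq2 1.32.0, with the genome build hg38. The annotation release and the strand setting of the counting are not given in the sources used here, so genes that overlap, or that share reads with near-identical copies, are uncertain. A further deposited table holds values on a log2 scale, per the file headers variance-stabilized. Over 1425 abundant genes the offsets between its columns and the log2 counts matched DESeq2 size factors to within 0.00013 on the log2 scale. The counts entered every main test, and the log2 table entered an alternative only.

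Symbols were found for 42265 of the 60646 identifiers, and positions for 58459 in GENCODE 29 (GRCh38). The 511 genes on chromosome Y, XIST and TSIX were left out of every test. Mitochondrial transcripts were not analysed here. Total counts per library ran from 34.3 to 49.3 M reads in DMSO and from 37.0 to 50.6 M reads in corin. Counting error is small for a gene at 10 CPM (counts per 1e6 counts) at this depth, and the spread between lines limited most tests. Replicate libraries differed by far more than counting noise: over genes with at least 280 reads in all, the smallest chi-square per gene of a replicate pair was 18.9, so no library was counted as a copy of another.

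For the comparisons across lines, the counts of the 2 libraries of a line and treatment were summed, so that the line was the replicate (14 profiles). edgeR 4.0.16 (R 4.3.3) was run with TMM scaling, filterByExpr and the quasi-likelihood F test, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. A single fit of the 14 profiles held a term per line, a corin effect for keloid lines and a corin effect for normal lines, and gave both responses and their difference. Keloid and normal lines were compared in the 7 DMSO profiles and in the 7 corin profiles. Responses of single lines, and PK4 against PNF4, came from a fit of 28 libraries in 14 groups. The p-values there measure only the spread between libraries of a line. Replicates 1 and 2 shared a passage in CRL-1762 (4), PK1 (7) and PK4 (2), where the spread may be technical. They differed in passage in PCS-201-021 (5 and 4), PK2 (8 and 4), PK3 (3 and 4) and PNF4 (3 and 4). The spread therefore mixes unlike replicates, and passage was not modelled. Log2 CPM values used a prior count of 2, and changes of single lines were taken from CPM with a pseudocount of 0.1. CPM are TMM-scaled, and errors are SD over lines unless given as SE.

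The 34 gene lists, the comparisons, the tests, the alternatives except those named at the end, and the rule for naming genes were fixed before the data were examined. The lists covered the CoREST complex, REST targets, genes induced by HDAC inhibitors, collagens, collagen processing, matrix glycoproteins, the TGF-beta pathway, contractile genes, matrix proteases, integrins, migration, S phase, G2 and mitosis, CDK inhibitors with p53 targets, apoptosis, interferon response, antigen presentation, inflammatory genes, cholesterol synthesis, hypoxia with glycolysis, stress response, metallothioneins, chromatin enzymes, HOX genes, genes reported as raised in keloid, Wnt, ribosomal proteins and immediate early genes. Another 6 lists held markers of keratinocytes, endothelium, melanocytes with Schwann cells, leukocytes, pericytes with muscle, and adipocytes. Lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry.

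Genes were named by a rule that took genes with an adjusted p under 0.05, an average log2 CPM of at least 3 and a regular symbol: for corin in keloid lines the 12 largest rises and 12 largest falls that went the same way in all 5 keloid lines, and for corin in normal lines 6 and 6. For the difference of the responses it took 8 and 8, for keloid against normal lines 10 and 10 in DMSO and 4 and 4 in corin, where all keloid lines lay on the same side, and for PK4 against PNF4 5 and 5. It added up to 2 rising and 2 falling members per list with the smallest p, and always KDM1A, HDAC1, HDAC2, RCOR1, CDKN1A, COL1A1, COL3A1, ACTA2 and MKI67. Some genes that the rule names are not reported here.

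Same-numbered libraries of a line shared a line and a passage. The correlation, across genes, of the gap between the 2 DMSO libraries with the gap between the 2 corin libraries was 0.18 in PCS-201-021, 0.31 in CRL-1762, 0.23 in PK1, 0.57 in PK2, 0.35 in PK3, 0.23 in PK4 and 0.11 in PNF4. The numbers were therefore read as pairing libraries, and a fit with each pair as a block was an alternative.

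The scripts were tested on simulated counts with 200 changed genes, drawn only from genes above a set average level. In the real data 67.1% of genes were called for corin in keloid lines and 51.6% in normal lines. The adjustment over genes was therefore stricter in simulation. The shares that follow are not the power of the real corin tests, nor that for genes of low counts. For corin in keloid lines the test recovered 73.1% of genes changed 1.5-fold, 92.5% of those changed 2-fold and 100% of those changed 4-fold. For corin in normal lines these shares were 13.4%, 76.1% and 95.5%, and for the difference of the responses 2.99%, 52.2% and 89.4%. For keloid against normal lines in DMSO they were 0%, 0% and 45.5%. A list shifted in simulation was called, and 0 of the 33 other lists were. Simulated genes were drawn independently of each other. The simulation therefore cannot test list calls where genes move together (estimated correlation 0.78 for G2 and mitosis).

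Alternatives were DESeq2 size factors, no filter on low counts, DESeq2 1.42.0, limma-voom, each line or library left out, unsummed libraries, replicate blocks, narrower fits and the estimated correlation. Alternatives chosen after seeing the data were total-count scaling, PCS-201-021 from its replicate 2 libraries only, PCS-201-021 without its DMSO replicate 1 library only, limma on the deposited log2 values, the replicate block for lists, and all alternatives for lists in comparisons other than corin in keloid lines. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.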

Results

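Messenger RNA was profiled in 5 keloid and 2 normal human fibroblast lines, each treated with DMSO or with corin, an inhibitor that joins a blocker of the demethylase LSD1 (KDM1A) to a blocker of the deacetylases HDAC1 and HDAC2 and so acts on the CoREST complex. With 2 libraries per line and treatment, 14 DMSO and 14 corin libraries were compared. Total counts ran from 34.3 to 49.3 M reads per DMSO library and from 37.0 to 50.6 M reads per corin library. The share of counts on FN1, the gene of fibronectin, was 2.59% in DMSO and 4.56% in corin, a gain of 1.97 ± 0.702 points (SD, n = 7 lines) seen in 7 of 7 lines (exact two-sided sign-flip permutation p = 0.0156, the smallest 7 lines allow). Genes with at least 10 reads rose from 16797 to 18367 per library, again in 7 of 7 lines (exact permutation p = 0.0156). The DMSO replicate 1 library of the normal line PCS-201-021 stood apart from the other 13 DMSO libraries. Its mean log2 CPM over the cholesterol list was 7.58 (others 4.77 to 5.75) and over the G2 and mitosis list 2.74 (others 4.18 to 6.29).

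**Figure D1:**
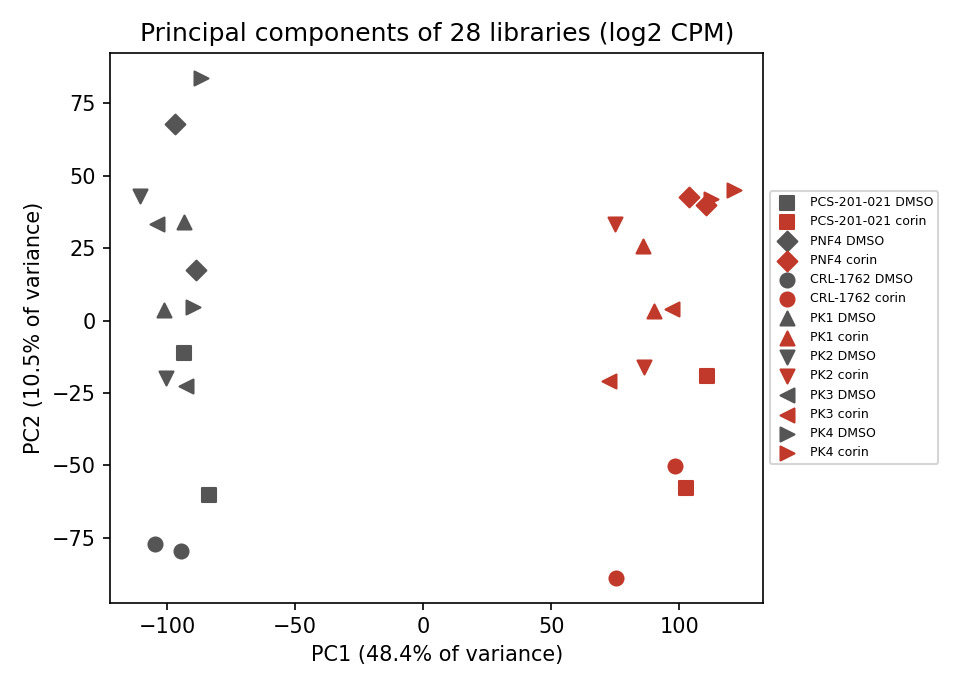
Principal components of the log2 CPM of 28 libraries, with PC1 (48.4% of variance) on the x axis and PC2 (10.5% of variance) on the y axis. Colour marks the treatment and the symbol marks the line. The 14 DMSO libraries lie at negative PC1 and the 14 corin libraries at positive PC1.

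The central question was what corin does to the transcripts of keloid fibroblasts. Genes of nerve cells were among the largest rises. KIF1A, a motor protein of axonal transport, went from 0.0807 ± 0.101 to 49.95 ± 22.0 CPM (SD, n = 5), a log2 change of 9.26 ± 0.63 (SE, edgeR adjusted p = 4.28e-06); its DMSO level rests on 32 reads over the keloid libraries. TUBB4A, a neuronal tubulin, changed by 8.77 ± 0.46 (SE, adjusted p = 1.67e-06). Genes of cell division fell: PLK1, a mitotic kinase, went from 81.3 ± 20.5 to 6.11 ± 4.49 CPM, a log2 change of -3.94 ± 0.26 (SE, adjusted p = 4.07e-06).

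Of 19628 genes tested with edgeR, 13180 changed in keloid lines, 6404 up and 6776 down, and 5545 of them at least 2-fold (3705 up, 1840 down). The balance depended on the scaling: 7112 rose and 6015 fell with DESeq2 size factors, and 5593 rose and 7856 fell with total counts. Among the 12 largest rises, others had log2 changes of 7.79 for SEMA6B, 7.68 for TPPP, 7.37 for CXADR, 7.33 for TTBK1, 6.62 for MAL2, 5.97 for NAT8L, 5.97 for TUBB2B, 5.89 for NFE2L3 and 5.84 for RIMS4. SEMA6B is a semaphorin of axon guidance and TPPP a tubulin-polymerizing protein. Among the 12 largest falls, others were RAD51AP1 at -4.13, CDCA8 at -3.98, AURKA at -3.80, HJURP at -3.78, GTSE1 at -3.76, CCNA2 at -3.74, PKMYT1 at -3.74, LMNB1 at -3.72, IQGAP3 at -3.72 and CCNB1 at -3.67. Each of these genes went the same way in 7 of 7 lines. Total-count scaling lowered the median log2 change of all genes by a shift of -0.11 in keloid and -0.16 in normal lines, so changes of that size depend on the scaling.

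**Figure D2:**
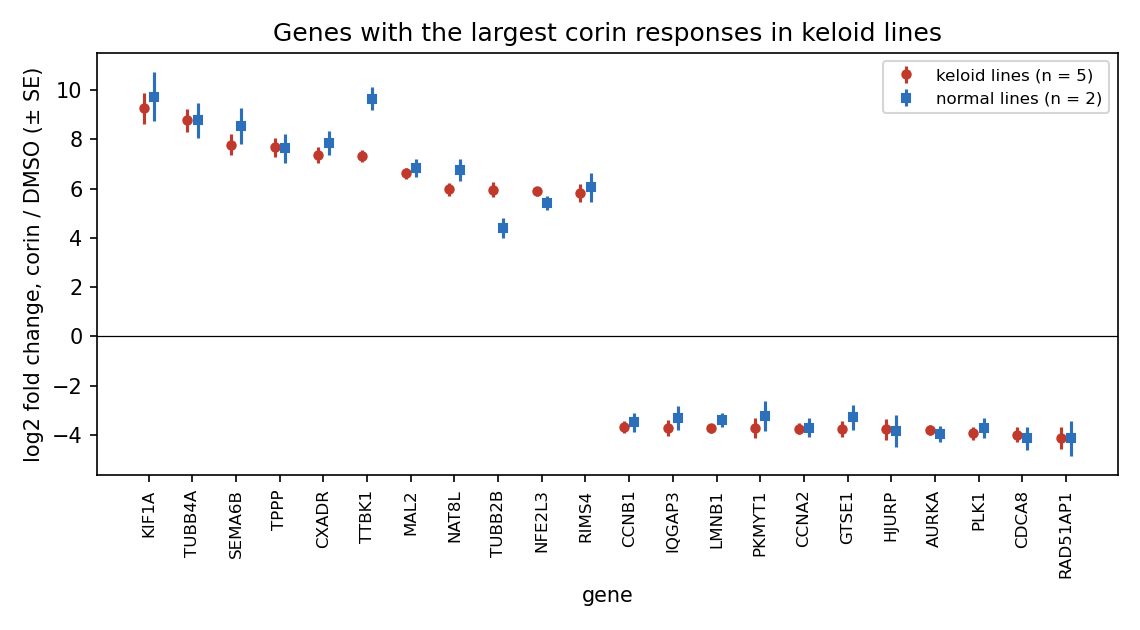
Log2 fold change of corin against DMSO, with SE from the edgeR fit, for genes among the 12 largest rises and 12 largest falls in keloid lines (x axis, genes). Red circles are keloid lines (n = 5) and blue squares normal lines (n = 2). Keloid values run from 9.26 for KIF1A to -4.13 for RAD51AP1, and each gene lies on the same side of 0 in normal lines.

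REST targets are neuronal genes held silent in other cells by REST and CoREST. Of 30 listed, 25 passed the filter on low counts. Of these, 24 rose and 1 fell, with a median log2 change of 3.55 (camera adjusted p = 5.07e-08). Genes silent in DMSO passed the filter only if they rose in corin, which favoured rising members. INA rose by 5.80 and SYP by 4.23, while TUBB3 fell by 0.53 on the log2 scale, a call that ended with DESeq2 size factors (adjusted p = 0.0578) and without CRL-1762 (adjusted p = 0.119). The list had an adjusted p = 0.262 with an estimated correlation. Of 12 genes known to be induced by HDAC inhibitors, 10 rose and 1 fell (median 1.10, adjusted p = 0.0013), and the adjusted p was 0.233 with an estimated correlation. HSPA2, a testis-enriched chaperone, rose by 3.81 and GADD45B, a stress sensor, by 1.18. Among 16 members of the CoREST complex and class I HDACs, 8 rose and 4 fell, and the list was not called (adjusted p = 0.271). KDM1A changed by -0.020 (adjusted p = 0.745) and RCOR1 by -0.18 (adjusted p = 0.135). RCOR1 was called with keloid lines only in the fit (edgeR adjusted p = 0.0383), with total counts (0.0141) and without either normal line. It was not called in the other alternatives. HDAC1 rose by 0.43, HDAC2 by 0.37, HDAC3 by 0.80 and KDM1B by 1.69, while ZMYM3 changed by -1.29 and HMG20B by -0.57. The direction of KDM1A turned under DESeq2 size factors (0.061). Of 36 chromatin enzymes, 21 fell and 4 rose (median -0.43, adjusted p = 0.00417), with an adjusted p = 0.462 with an estimated correlation. CREBBP, an acetyltransferase, changed by -1.08 and SETD7 by -0.82, whereas TET3 rose by 1.27 and HDAC5 by 0.71.

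Cell cycle genes fell without exception in keloid lines. All 38 measured G2 and mitosis genes fell (median -3.08, adjusted p = 7.29e-14), and all 36 S phase genes fell (median -2.64, adjusted p = 1.43e-10); the adjusted p was 0.371 and 0.405 with an estimated correlation. MKI67, the Ki-67 antigen, went from 140 ± 53.1 to 18.9 ± 14.3 CPM (SD, n = 5), a log2 change of -3.08. CDK inhibitors and p53 targets went both ways, with 8 up and 11 down of 25 (median -0.08, mean 0.07, adjusted p = 0.897). CDKN1A, which encodes the inhibitor p21, rose by 0.79 and GADD45A by 1.01, while CDKN2C changed by -1.98 and TP53I3 by -1.33. Of 29 apoptosis genes, 10 rose and 15 fell, and the median (-0.28) and the mean (0.47) had opposite signs (adjusted p = 0.422). BCL2L11 rose by 2.67 and PMAIP1 by 1.70, both promoters of cell death, while FAS changed by -1.26 and CFLAR by -1.17.

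Among matrix genes, which define the keloid scar, the collagen list was called and the other matrix lists were not. Of 21 collagen chains, 11 rose and 2 fell (median 0.39, adjusted p = 0.0354), and the list had an adjusted p = 0.605 with an estimated correlation. Its call also ended without PK1, PK2 or PK3. COL1A1, the main chain of fibrillar collagen, rose from 24004 ± 10207 to 35171 ± 12165 CPM (SD, n = 5), a log2 change of 0.59 (adjusted p = 0.00424). COL3A1 changed by -0.37 (edgeR adjusted p = 0.013), COL14A1 by 2.47, COL8A2 by 1.52 and COL16A1 by -0.33. The COL3A1 call ended without PK2 (edgeR adjusted p = 0.0501), with the replicate block (0.0718) and with libraries not summed (0.346). The COL16A1 call ended with the replicate block (edgeR adjusted p = 0.0641) and with libraries not summed (0.226). Both calls also ended with limma on the deposited log2 values (adjusted p = 0.0766 for COL3A1 and 0.0613 for COL16A1). Among 22 collagen processing genes 7 rose and 6 fell (adjusted p = 0.897); P3H2 rose by 3.07 and PLOD2 by 1.30, and PLOD3 changed by -0.60. Among 29 matrix glycoproteins 8 rose and 4 fell (adjusted p = 0.514); TNC rose by 0.78, and EMILIN1 changed by -1.34. Of 25 genes reported as raised in keloid, 12 rose and 7 fell (adjusted p = 0.422), among them CTHRC1 at -0.86. Of 25 matrix proteases and inhibitors 13 rose and 4 fell (adjusted p = 0.102); TIMP4 rose by 3.60 and PLAT by 1.62, and MMP14 changed by -1.12 and FAP by -0.42.

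The TGF-beta list, the pathway most tied to scarring, was not called (12 up, 10 down of 28; adjusted p = 0.355). CCN1 rose by 1.55 and TGFBR2 by 1.42, while TGFB1I1 changed by -2.01 and LTBP2 by -0.69. Of 18 contractile genes 6 rose and 2 fell (adjusted p = 0.355). ACTA2, smooth muscle actin and a marker of myofibroblasts, changed by 0.60 (edgeR adjusted p = 0.0396). Its call ended without CRL-1762 (edgeR adjusted p = 0.0584), PK1 (0.133) or PK3 (0.0596). It also ended with libraries not summed (0.0545) and with total counts (0.0677). MYH11 rose by 2.21 and CALD1 by 0.62, and SYNPO2 changed by -0.58. Integrins rose, with 13 up and 3 down of 18 (median 0.83, adjusted p = 0.00808; adjusted p = 0.371 with an estimated correlation). ITGB4 rose by 3.99 and ITGA1 by 0.96, while ITGA11 changed by -0.46 and ITGA8 by -0.63. The ITGA11 call ended with the replicate block (edgeR adjusted p = 0.0827) and with libraries not summed (0.199). The ITGA8 call ended without PK3 (edgeR adjusted p = 0.0547). Of 31 migration genes 15 rose and 7 fell (adjusted p = 0.18): SNAI1 rose by 1.52 and FGFR1 by 0.87, and FGF7 changed by -1.99. Of 30 Wnt genes 17 rose and 6 fell (adjusted p = 0.0516): WNT2B rose by 3.80, and AXIN1 changed by -0.93 and WNT5A by -0.76.

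Inflammatory genes rose, with 20 up and 3 down of 25 (median 1.51, adjusted p = 0.000239; adjusted p = 0.371 with an estimated correlation). The chemokine CXCL6 rose by 4.92, TNFAIP6 by 3.46 and IL6 by 1.49, and NFKB1 changed by -0.94. Interferon genes went both ways (11 up, 10 down of 28; adjusted p = 0.725), with OASL at 4.02, IFIT1 at 1.44, SAMD9L at -1.47 and STAT2 at -1.07. Of 22 antigen presentation genes 10 rose and 4 fell (adjusted p = 0.271). Metallothioneins, which bind zinc and copper, rose in 6 of 7 genes (median 1.74, adjusted p = 0.0124; adjusted p = 0.371 with an estimated correlation), among them MT1G by 6.09 and MT1E by 1.35. Cholesterol genes had 11 up and 5 down of 23 (adjusted p = 0.271), with STARD4 at 1.36, NSDHL at -1.11 and FDPS at -0.88. Hypoxia and glycolysis genes had 11 up and 6 down of 28 (adjusted p = 0.271), with NDRG1 at 1.86 and PFKL at -0.92. Stress response genes had 7 up and 9 down of 23 (median -0.13, mean 0.01, adjusted p = 0.833), with ATF3 at 2.04 and SHMT2 at -0.89. Immediate early genes had 8 up and 3 down of 15 (adjusted p = 0.0489; adjusted p = 0.371 with an estimated correlation), a call that also ended with DESeq2 size factors and without PCS-201-021, PK2, PK3 or PNF4, with IER3 at 2.24 and FOSL1 at -2.60. Ribosomal protein genes had 16 up and 0 down of 33, with a median of 0.22 (adjusted p = 0.00808, and 0.736 with an estimated correlation), and RPL15 rose by 0.53. Over keloid and normal lines their share of counts changed by 0.13 ± 0.21 points (SD, n = 7) and rose in 5 lines (exact permutation p = 0.172). HOX genes, which record body position, had 13 up and 4 down of 34 (median 0.67, adjusted p = 0.0412; adjusted p = 0.574 with an estimated correlation), a call that also ended with DESeq2 size factors and without CRL-1762, PK2, PK3 or PNF4, with HOXB2 at -1.85 and HOXB3 at -0.75.

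Markers of other cell types rose as well, among those that passed the filter on low counts. These were 11 of 14 endothelial, 7 of 13 melanocyte and Schwann cell, and 12 of 18 keratinocyte markers. For pericytes and muscle they were 10 of 12, for adipocytes 6 of 10 and for leukocytes 8 of 19. The filter used DMSO and corin profiles together, so a rise in corin helped to select the markers tested. Endothelial markers had 8 up and 0 down of 11 (median 2.59, adjusted p = 0.00222), with ESAM at 5.73 and EGFL7 at 1.60. Melanocyte and Schwann cell markers rose in 7 of 7 (median 2.37, adjusted p = 0.00808), with ERBB3 at 4.21 and PMEL at 2.37. Keratinocyte markers had 8 up and 1 down of 12 (adjusted p = 0.028), pericyte and muscle markers 7 up and 1 down of 10 (adjusted p = 0.0342), and adipocyte markers 4 up and 0 down of 6 (adjusted p = 0.0342), with CEBPA at 5.34 and FABP4 at 5.27. Leukocyte markers had 5 up and 0 down of 8 (adjusted p = 0.089), with KIT at 1.51. With an estimated correlation the adjusted p was 0.233 for the endothelial list and 0.371 for each of the other 5. In all, 17 of 34 lists were called, 14 up and 3 down, and 0 were called with an estimated correlation. With fry 25 were called. That test asks whether a list moved at all, not whether it moved more than other genes. Regrouped keloid profiles called up to 18 lists, where the real grouping of these profiles called 16. No regrouping divided the corin profiles evenly, so none was free of the drug effect. This comparison therefore cannot test the number of lists called, which stays weak evidence. Counts adjusted over the list alone matched those above except for TGF-beta (13 up), contractile (5 up), integrins (14 up), stress response (10 down), HOX (12 up), ribosomal (13 up) and pericyte (8 up) lists.

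**Figure D3:**
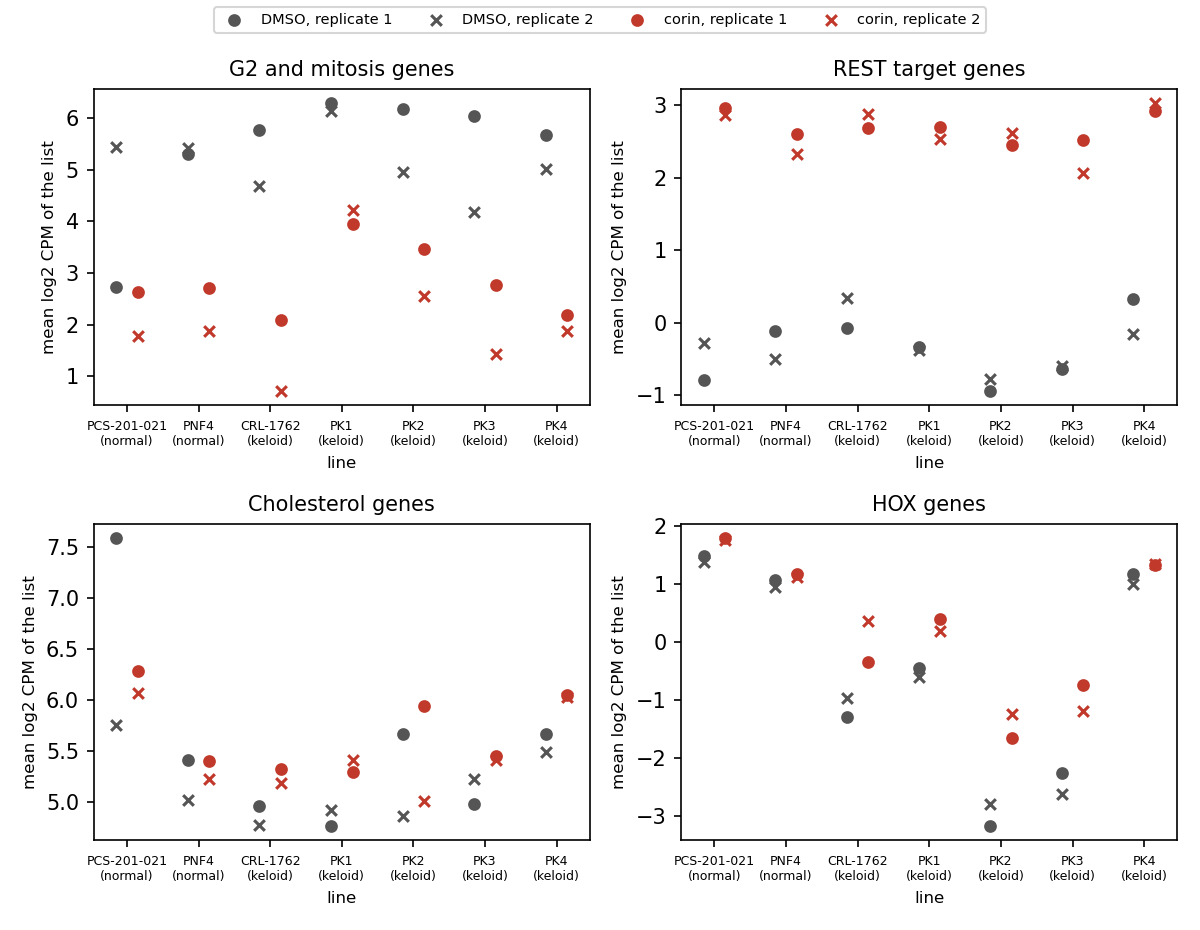
Mean log2 CPM (y axis) of the G2 and mitosis, REST target, cholesterol and HOX lists in each library of the 7 lines (x axis). Grey is DMSO and red is corin; circles are replicate 1 and crosses replicate 2. REST targets lie between 2.07 and 3.03 in every corin library and between -0.94 and 0.34 in every DMSO library, and the DMSO replicate 1 library of PCS-201-021 lies at 7.58 for cholesterol.

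The same comparison in the normal lines asked whether the response belongs to keloid cells. KIF1A rose by 9.73, TTBK1 by 9.66, TUBB4A by 8.77, SEMA6B by 8.54, CXADR by 7.86 and TPPP by 7.64 on the log2 scale. ACKR4, a chemokine-scavenging receptor, changed by -4.60 ± 0.61 (SE, n = 2, edgeR adjusted p = 0.000429), CDCA8 by -4.14, RAD51AP1 by -4.14, AURKA by -3.96 and HJURP by -3.84. REST targets had 20 up and 0 down of 25 (median 3.56, adjusted p = 4.95e-09), and G2 and mitosis genes 37 down of 38 (median -2.82, adjusted p = 1.01e-13); the adjusted p was 0.209 and 0.468 with an estimated correlation. Adjusted over the list alone, 23 REST targets rose and 38 G2 and mitosis genes fell. Of 34 lists, camera called 10 up and 3 down in normal lines. An estimated correlation left 0 called, and fry called 23. In the odd PCS-201-021 pair of replicate 1 the mean G2 and mitosis response was -0.10, against -3.66 in replicate 2. In normal lines 10122 of 19628 genes changed with edgeR (4960 up, 5162 down), and 6733 without PNF4. With DESeq2 size factors 5270 rose and 4735 fell, and with total counts 4199 rose and 6543 fell. With 2 lines the spread came mainly from the keloid lines.

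Keloid and normal responses were close to each other. Of the genes called in both, 9687 in number, all went the same way: 4718 up and 4969 down, where independent lists would share 1618 and 1782. Across genes, which are not independent replicates, the log2 changes had r = 0.94, and 62.4% of genes went the same way in all 7 lines, where chance gives 1.56%. The comparisons share no library, but they share a fit and a scaling. The difference of the responses was called for 0 of 19628 genes with edgeR (750 at an unadjusted p under 0.05, smallest adjusted p = 0.258). DESeq2 called 17 and limma-voom 0, and edgeR called 12 without PNF4 and 3 with no filter. The test recovered 52.2% of simulated 2-fold and 2.99% of simulated 1.5-fold differences, so many differences of that size would be missed. Among lists, 3 were called higher and 4 lower in keloid lines, and 0 with an estimated correlation. The cholesterol list differed by 0.63 (mean log2 change 0.33 ± 0.13 in keloid, -0.29 ± 0.42 in normal lines; adjusted p = 4.6e-23), and by 0.09 without the DMSO replicate 1 library of PCS-201-021, where the call ended (adjusted p = 0.116). Adjusted over the list alone, 13 of 23 cholesterol genes differed, and 0 over all genes. HOX genes differed by 0.94 (1.30 ± 0.67 against 0.36 ± 0.25; adjusted p = 6.37e-05). The sign of the HOX response in normal lines depends on the statistic, with a list median of -0.49 and a mean of 0.28 (adjusted p = 0.713). The adjusted p of both was 0.722 with an estimated correlation.

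Single lines gave 5674 called genes in PCS-201-021, 5192 in CRL-1762, 4721 in PK1, 4797 in PK2, 5097 in PK3, 6009 in PK4 and 5569 in PNF4, of 21392 tested with edgeR. In all 7 lines 1485 genes were called up and 851 down, while 23 genes were called up in some line and down in another. These counts depend on the fit. With only the libraries compared, calls per line ran from 1580 in PK2 to 7466 in PK1. With replicate pairs as a block they ran from 6552 in PK1 to 7662 in PK4. The responses of pairs of lines had r between 0.830 and 0.944 across genes, with means of 0.891 among keloid lines and 0.888 between keloid and normal lines.

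Keloid and normal lines were then compared without drug. In DMSO the test called 0 of 19880 genes with edgeR (820 at an unadjusted p under 0.05, smallest adjusted p = 0.845), DESeq2 called 37 and limma-voom 0; leaving out PK4 or PNF4 gave 2 or 1. The design recovered 0% of simulated 2-fold and 45.5% of simulated 4-fold differences. HOX genes were lower in keloid lines (median -1.83, adjusted p = 5.91e-12), as were cholesterol genes (median -0.98, adjusted p = 2.12e-11) and collagen processing genes (median -0.12, adjusted p = 0.0249). S phase genes (median 0.54, adjusted p = 1.8e-20), G2 and mitosis genes (median 0.55, adjusted p = 3.04e-14), metallothioneins (median 0.54, adjusted p = 0.0218) and hypoxia genes (median 0.23, adjusted p = 0.0247) were higher. Adjusted over the list alone, 1 metallothionein differed. All 7 lists had an adjusted p = 0.798 with an estimated correlation. The odd PCS-201-021 library lay at 7.58 for cholesterol and 2.74 for G2 and mitosis; without that line the cholesterol list had an adjusted p = 0.932 and collagen processing 0.0857, and the metallothionein difference turned to the other direction (adjusted p = 0.709). Without that library alone, the mean G2 and mitosis difference went from 0.52 to 0.20 and the S phase difference from 0.56 to 0.38, both still called. The mean cholesterol difference went from -0.88 to -0.33 without that library. The hypoxia call ended without PK3 or PNF4, the metallothionein call without PK4, and the collagen processing call also without PK1, PK2, PK3 or PNF4.

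Under corin the test called 0 of 21726 genes with edgeR (641 at an unadjusted p under 0.05, smallest adjusted p = 1.00), DESeq2 called 23 and limma-voom 0. HOX genes stayed lower in keloid lines (median -1.22, adjusted p = 3.64e-16), as did collagen processing (median -0.28, adjusted p = 0.000281) and collagen genes (median -0.46, adjusted p = 0.000633). Contractile (median 0.43, adjusted p = 0.000731), S phase (median 0.64, adjusted p = 0.000731) and G2 and mitosis genes (median 0.61, adjusted p = 0.0347) were higher. All 6 had an adjusted p = 0.999 with an estimated correlation, and the collagen call ended without the replicate 1 libraries of PCS-201-021 (adjusted p = 0.209). The G2 and mitosis difference turned to the other direction without PK1 (adjusted p = 0.67), and its call ended without PCS-201-021, PK2 or PNF4. Without PK1 the mean S phase difference went from 0.42 to 0.10 and its call ended, as it did without PNF4. The collagen and collagen processing calls ended without PCS-201-021, and the contractile call without CRL-1762 or PNF4.

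PK4 and PNF4 are the keloid and normal lines that carry the same number. The labels do not state whether they came from the same patient, and the comparisons of keloid with normal lines treat them as independent. They were the closest of 21 pairs of lines in DMSO (SD of log2 differences 0.641). Their responses to corin had r = 0.944 across genes, the highest of the pairs. Each pair that held CRL-1762 or PCS-201-021 ranked 9 or later of 21 in DMSO distance. CRL-1762 and PCS-201-021 were themselves the farthest pair (1.21). TM4SF1, a membrane protein of the tetraspanin-like family, stood at 24.9 ± 13.2 CPM in PK4 and 0.181 ± 0.0412 CPM in PNF4 (SD, n = 2 libraries), a log2 difference of 7.08 (edgeR adjusted p = 0.00337). SRGN differed by 5.73 (116 ± 130 against 2.17 ± 0.957 CPM), SCN9A by 4.76, SCUBE3 by 4.21 and TINAGL1 by 4.04, and C1orf115 was lower in PK4 at -3.02. None of these named genes was called when only the 4 libraries entered the fit (edgeR adjusted p from 0.142 for TM4SF1 to 0.549 for SRGN). Without PK4 DMSO replicate 2 the differences were 3.45 for SRGN, 3.43 for SCN9A, 3.42 for TINAGL1 and -2.60 for C1orf115. In all, 40 of 21392 genes were called, 33 higher in PK4 and 7 lower. The count depends on single libraries, with 1 to 88 calls when 1 was left out and 0 when only the 4 libraries entered the fit.

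Whether corin moves keloid cells toward normal cells was asked with separate libraries for the baseline (replicate 1) and the response (replicate 2). No gene was called at baseline (0 of 16993 with edgeR), so the 500 genes with the smallest p were used. Of these, 361 (72.2%) responded against their baseline difference, beside 53.5% of all genes; the shift per line was 0.64 ± 0.16 (SD, n = 5), in 5 of 5 lines (exact two-sided permutation p = 0.0625, the smallest possible). With the libraries exchanged, 250 (50%) did, beside 48.1% of all genes, and the shift was 0.05 ± 0.18, in 4 of 5 lines (SD, n = 5; exact permutation p = 0.562). The shift therefore did not hold with the other libraries, and the replicate 1 baseline includes the odd PCS-201-021 library.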

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

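Tests chosen only after the result was seen were those on the PCS-201-021 library, on HOX genes and on endothelial cells; the test of library depth was set earlier. Among the 67 series of 5 keloid lines checked for a line far from the others, 3 stood out, where chance gives 3.35. The median response of the CoREST list was -0.029 in PK1 (others 0.16 to 0.22), that of the Wnt list 0.78 in PK1 (others 0.49 to 0.57) and that of immediate early genes 1.05 in PK3 (others 0.42 to 0.59).

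The response to corin differed between keloid and normal lines for 7 of 34 lists (camera adjusted p, median difference in log2): integrins (0.0162, -0.26), G2 and mitosis (0.0273, -0.23), cholesterol (4.6e-23, 0.62), hypoxia (0.0273, -0.17), metallothioneins (0.0162, -0.67), HOX (6.37e-05, 0.92) and ribosomal genes (0.0273, 0.08). With an estimated correlation the adjusted p ran from 0.722 to 0.855 for these lists, so none was called, and fry called 0. The integrin, hypoxia and metallothionein calls rest on PCS-201-021: they ended without that line, and the median response of PNF4 lay below the keloid lines for integrins (0.65; keloid 0.72 to 0.84) and within them for hypoxia (0.29; keloid -0.05 to 0.35) and metallothioneins (1.99; keloid 1.26 to 2.11). With PCS-201-021 taken from replicate 2 these 3 calls ended too, the ribosomal difference turned from 0.083 to -0.013 (adjusted p = 0.72), and the G2 and mitosis difference turned from -0.26 to 0.34 and was called in that direction (adjusted p = 0.000618).

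The cell cycle and cholesterol differences involve the DMSO replicate 1 library of PCS-201-021, at 7.58 for cholesterol and 2.74 for G2 and mitosis. Without that library the mean cholesterol difference went from 0.63 to 0.09 (SE between lines 0.24) and its call ended because the difference shrank (adjusted p = 0.116), and the G2 and mitosis difference went from -0.26 to 0.08 (SE 0.29; adjusted p = 0.316), so this library may account for both. A corin-treated culture under a DMSO label is argued against by the REST targets, at -0.79 in this library, against 2.07 to 3.03 in corin libraries. For cholesterol, the corin libraries argue against a state shared by both replicate 1 cultures only if it would outlast corin treatment. Whether it would was not tested. The corin libraries differed by 0.21, where the DMSO libraries differed by 1.83. For other genes such a state stays open. On PC2 both replicate 1 libraries of PCS-201-021 lay apart (-60.1 in DMSO and -57.8 in corin) from replicate 2 (-11.1 and -19.0). The replicates of PK2 lay as far apart (43.1 and 33.3 against -19.9 and -16.1). Replicates 1 and 2 were of passages 5 and 4 in PCS-201-021 and of passages 8 and 4 in PK2. Passage and replicate therefore cannot be told apart in either line. A state of the odd PCS-201-021 DMSO culture, such as density or serum, was not tested, and neither was a biological difference, which 2 normal lines cannot settle.

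HOX genes were lower and responded more in keloid lines, with adjusted p = 0.798 and 0.722 with an estimated correlation. Keloid state as the whole cause is argued against by PK4, since 4 of 5 keloid lines, not 5, lay below both normal lines in DMSO (PK4 1.09, normal lines 1.02 and 1.43), and PK4 responded by 0.25, between the normal lines (0.14 and 0.34). The response followed the DMSO level of the line, measured in separate libraries (r = -0.97, n = 7, exact permutation p = 0.00218, 0.00377 adjusted over 2 relations; r = -0.98 without the 2 farthest lines). With the libraries exchanged r was -0.98. The permutation takes the 7 lines as independent. PK4 and PNF4 may share a patient, were the closest pair in DMSO and had near-equal HOX levels (1.09 and 1.02). The permutation p may therefore be too small. The body site of each line, which sets HOX genes, may therefore explain the difference and was not tested; a general rise of genes low in DMSO stays open too.

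More genes were detected after corin. Among markers that passed the filter, those of 5 other cell types rose, although these lists had adjusted p = 0.233 to 0.371 with an estimated correlation. Library depth is argued against, since at an equal depth of 34.3 M reads the gain was 1275 ± 130 genes (SD, n = 7), in 7 of 7 lines (exact permutation p = 0.0156). Endothelial cells in the treated cultures stay open. PECAM1 (gain 0.204 ± 0.142 CPM), VWF (1.34 ± 0.482) and CDH5 (1.10 ± 0.844) each gained less than EGFL7 (11.9 ± 3.98) in 7 of 7 lines, but EGFL7 stood at 6.15 CPM in DMSO, and no endothelial profile was measured here. A loss of silencing by the inhibitor in the fibroblasts themselves may explain both, but other cells were not excluded.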

How the results depend on the processing

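Alternatives chosen only after the data were seen were total-count scaling, PCS-201-021 from replicate 2 or without its DMSO replicate 1 library, limma on the log2 values, the replicate block for lists, and all alternatives for lists other than corin in keloid lines. For the genes named by the rule, results were counted once per gene and alternative. Under corin in keloid lines 2647 such results kept direction and side of the threshold, 33 lost the call, 5 gained it and 7 reversed. In normal lines all 228 results kept both. Most of these genes were named for a large change or a small p in the same data, so the counts say little about genes at large. Calls for corin in keloid lines ran from 11281 to 14041, and from 12123 to 13151 in leave-one-out fits. Those in normal lines ran from 6733 (without PNF4) to 10288 in leave-one-out fits. The difference of the responses gave 3 genes with no filter, 17 with DESeq2 and 0 to 12 in leave-one-out fits (12 without PNF4). Keloid against normal lines in DMSO gave 37 with DESeq2 and 0 to 2 in leave-one-out fits (2 without PK4), and in corin 23 with DESeq2; the cause was not tested. With only the libraries compared, single lines gave 2959 (PCS-201-021), 2995 (CRL-1762), 7466 (PK1), 1580 (PK2), 3214 (PK3), 3388 (PK4) and 6602 (PNF4), so the counts of PK1 and PNF4 rose and the others fell; the cause was not tested. Without 1 replicate, where the lone library is assumed to vary like the other groups, they gave 3414 to 4052 (PCS-201-021), 2680 to 4605 (CRL-1762), 2241 to 2747 (PK1), 2810 to 3522 (PK2), 2667 to 3722 (PK3), 3581 to 5014 (PK4) and 3264 to 3455 (PNF4). PK4 against PNF4 gave 464 with no filter, 186 with DESeq2, 0 with only the libraries compared, and 1 to 88 without 1 replicate (1 without PNF4 replicate 1, 88 without PK4 replicate 1). With each replicate pair as a block, the counts were 12493 in keloid lines, 9803 in normal lines and 0 for the difference. Single lines then gave 7448 (PCS-201-021), 6985 (CRL-1762), 6552 (PK1), 6601 (PK2), 6925 (PK3), 7662 (PK4) and 7272 (PNF4), each above its count without the block. PK4 against PNF4 gave 36 with the replicate number as a block across the lines. Lists called for corin in keloid lines were 0 with an estimated correlation, 25 with fry, 15 with size factors and 14 to 17 in leave-one-out fits. KDM1A, not called, reversed to 0.061 with size factors, 0.061 with DESeq2, 0.067 in patient-derived lines, 0.039 unsummed, 0.042 with the block and 0.073 with limma on the log2 values, and ran from -0.043 to 0.068 in leave-one-out fits; under total-count scaling it was called at -0.13. For the difference, G2 and mitosis reversed with PCS-201-021 from replicate 2 (0.000618; leave-one-out 4.19e-09 to 0.89) and so did ribosomal genes (0.72; leave-one-out 0.000264 to 0.886), both also without PCS-201-021, and G2 and mitosis without its DMSO replicate 1 library (0.316). In DMSO metallothioneins reversed without PCS-201-021 (0.709; leave-one-out 0.000762 to 0.709), and in corin G2 and mitosis without PK1 (0.67; leave-one-out 6.62e-07 to 0.67). The share of 500 genes responding against their baseline was 50% with libraries exchanged, beside 72.2%. The cause of these was not tested.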

Other observations

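The test that regrouped gene families used merged name stems chosen after the data were seen, as was the choice of genes on DMSO libraries alone, while the other tests by DMSO level and those by other splits were set earlier. Splits of the 10 keloid profiles into 5 and 5 (100 of 126 drawn) cannot exclude chance for the genes called. Of 100 splits 1, the real one with 13172 genes, called as many, and the highest other called 0. Most of these splits put DMSO and corin profiles of a line in the same group. That leaves the drug effect in the spread, so few calls were likely in advance. Splits that part all 5 pairs number 16, too few for a share under 0.05; the highest other of the 11 drawn called 0. For lists, 16 of 100 splits called at least the real 16, and the highest other called 18 (15 among those parting all pairs). With 5 corin profiles no split divides them evenly, so each keeps part of the drug effect. Chance was not excluded for the number of lists called, and these splits cannot test it.

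Genes low in DMSO rose more than abundant genes: the median response of the lowest 20% exceeded that of the highest 20% by 1.33 ± 0.11 (SD, n = 7 lines, log2) in 7 of 7 lines, with level and response from separate libraries. Genes entered this test by their counts in DMSO and corin together, so a rise in corin helped to select genes low in DMSO; with genes chosen on the DMSO libraries of the level alone the gap was 0.54 ± 0.15, in 7 of 7 lines. Of 110 gene families, 9 held more rising and 20 more falling members than protein-coding genes at large, and 0 did in any of 20 shuffles of the calls, although genes of a family are not independent. Genes named as collagens had 24 up and 2 down of 39 (adjusted p = 0.00998; 27 up with size factors and 20 with total counts). Potassium channel genes had 40 up and 3 down of 62 (Fisher adjusted p = 6.44e-05). Proteasome genes had 1 up and 40 down of 48 (Fisher adjusted p = 5.9e-08). Mitochondrial ribosomal proteins had 1 up and 54 down of 77 (Fisher adjusted p = 3.57e-06). Families were tested among genes that passed the filter on DMSO and corin together, and were not matched for level in DMSO. How much of the rise or fall of a family reflects this selection or its level was not tested.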
